A study of Mus musculus with 2 samples.

How the data were processed

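The data are 2 spatial libraries of mouse calvarial bone, 1 per group, harvested at day 7. The Blank library is from a bone defect without collagen/nHA material and the Col_nHA library from a defect with it. The deposited matrices hold raw UMI counts per gene and barcode, with 31053 genes and 4992 barcodes in each, and no tissue filter had been applied to them. Per the labels, the authors used Space Ranger with genome build mm10, and the version is not given in the sources used here; the matrix headers name Cell Ranger 4. The labels describe fresh-frozen spatial sections, while the extraction text in the labels describes a droplet single-cell library, and the barcode number and the processing tool go with the former. No image or spot coordinates were used here, so nothing is said about where a spot lay.

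Spots over tissue were the barcodes above an Otsu threshold on the log10 of total UMIs, set in each section on its own, at 3667 UMIs in Blank and 4688 in Col_nHA. They held 88.1% of the 34868368 Blank UMIs and 89.1% of the 45137685 Col_nHA UMIs. The UMI totals did not part cleanly, with 265 Blank and 214 Col_nHA barcodes within 10% of the threshold. UMIs of the spots over tissue, 30705849 in Blank and 40202268 in Col_nHA, were summed per section and scaled to CPM, which puts both sections on a common library total. Ratios are Col_nHA over Blank. With 1 library per group there is no estimate of spread between animals or sections, so intervals are exact 95% intervals of counts (conditional binomial for ratios, Poisson for CPM, Clopper-Pearson for shares) and cover counting error only. For the 95 named genes outside the 12 highest and 12 lowest, the upper bound lay a median of 4.59% above the ratio. A gene with 0 UMIs in 1 section was set at a floor of 3 counts. Genes with at least 10 CPM in one or both sections were counted as higher or lower at 2-fold.

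Before the data were examined, 32 gene lists with 386 entries were fixed, for cell types, cell states and other tissues. Of 369 symbols, 366 were found; Ahsp, Ca9 and Ccn2 were not. Of the 31053 gene IDs, 30934 matched a gene name table, and positions are those of a RefSeq table on GRCm38.p6. A list was described by the median log2 ratio of its members with at least 5 CPM in one or both sections, if it had 4 or more. The percentile of that median was taken among 10000 random lists of the same size matched in 20 bins of mean expression, and a list stood apart below percentile 2.5 or above 97.5. Random lists treat genes as independent, so the percentile describes these 2 libraries and is no test of the treatment. The naming rule took the 12 highest and 12 lowest ratios among genes with at least 50 CPM, leaving out mitochondrial, ribosomal protein, haemoglobin and unnamed genes, and from each list the 2 most abundant members and the 2 with the largest absolute log2 ratio among those with at least 10 CPM. This named 119 genes.

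Shares of spots with a UMI were taken after thinning each spot to 2000 UMIs. For regions, the spots of both sections were scaled to 10000 counts, log-transformed and reduced to 30 principal components of 2000 highly variable genes, without batch integration. Leiden clustering used 15 neighbours and a resolution of 0.6. Regions carry a number and leading genes only, and ratios within a region were taken where each section had at least 50 spots. Spearman rho was taken across spots between the share of UMIs in each list and in the osteoblast or macrophage list, without shared genes. The software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, which was used for TMM factors alone.

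The calculations were tested on simulated data. With 9494 simulated genes, 95.5% of the intervals held the true ratio, 100% of genes simulated at 2.5-fold and 0% of those at 1.5-fold were counted as 2-fold. Of random lists 6% stood apart, as did 100% of lists with 8 of 12 raised members, and the threshold sorted 99.2% of simulated spots rightly. Those spots were drawn from well-parted groups of UMI totals, unlike the totals here, so that share is not the accuracy of the tissue call. Alternatives fixed in advance were other UMI thresholds, every barcode, a Gaussian mixture for the number of spots alone, TMM, median-of-ratios and a total without mitochondrial, ribosomal and haemoglobin genes for scaling, the mean of per-spot CPM, other CPM minimums, no thinning or 500 UMIs, resolutions of 0.3 and 1.0, and leaving out spots with over 2% of UMIs in the other tissue lists. Leaving out spots by those lists together with 11 choroid plexus genes was added after the data were seen. Those genes were picked from known markers after Ttr was noticed.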

Results

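RNA was counted on a spatially barcoded array in 2 frozen sections of mouse calvarial bone, the flat bone of the skull roof, harvested 7 days after the bone defects were implanted or left without material. The Blank section came from a defect without collagen/nHA material, and the Col_nHA section from a defect with it. Each group held 1 section, so no difference between the groups has a replicate check, and no p-value is given. All intervals are exact 95% intervals that cover counting error only, and every ratio compares these 2 libraries rather than the 2 treatments. The Blank file held 34868368 unique molecular identifiers (UMIs) over 4992 barcodes, and the Col_nHA file held 45137685 over the same number. Barcodes above a UMI threshold set in each section were taken as spots over tissue, which gave 2249 spots in Blank with a median of 9733 UMIs and 3423 genes, and 2471 spots in Col_nHA with a median of 13815 UMIs and 3994 genes. A spot can hold several cells, so the values below describe spots and sections, not cells.

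The first comparison asked which transcripts differed in abundance between the section with the material and the section without it. In the Col_nHA section, the list of genes of macrophages that take up lipid or foreign material lay higher. So did the list of genes of macrophage fusion and of osteoclasts, the cells that resorb bone. A list does not tell which of these cells held the transcripts. Transcripts of cell division, glycolysis and chemokines were also more abundant in Col_nHA. Spp1, which encodes the matrix protein osteopontin, stood at 8498 CPM in Col_nHA and 1481 CPM in Blank, a ratio of 5.74 (5.68 to 5.79). In the Blank section, transcripts of osteocalcin, mast cells, fat, red blood cells and keratinised skin were more abundant. Of 9855 genes with at least 10 CPM in one or both sections, 180 were at least 2-fold higher in Col_nHA and 335 were at least 2-fold lower, and the median log2 ratio of all 9855 genes was 0.015. The sections also differed in the skin, muscle, fat and choroid plexus transcripts they held, as described further on. Without the spots rich in those tissues, a setting chosen after the data were seen, the counts were 153 higher and 211 lower, of which 112 and 165 were among the genes counted above.

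The lipid-associated and foreign-body macrophage list had a median log2 ratio of 0.69, percentile 100 among 10000 random lists matched on expression, with 3 of 12 measured members at least 2-fold higher and none at least 2-fold lower. Those 3 were Spp1, Gpnmb, a glycoprotein of the macrophage endolysosome, at 3.92 (3.82 to 4.01), and the integrin gene Itgax at 2.57. Apoe, which encodes a lipid carrier and was the most abundant member in Blank at 4734 CPM, stood at 3787 CPM in Col_nHA, a ratio of 0.80. The general macrophage and monocyte list had a median log2 ratio of 0.18 (percentile 91.5), and none of its 14 measured members differed by 2-fold; without the spots rich in other tissues it lay above the random range, at 0.29 (percentile 98.4). Within it the complement gene C1qb stood at 1.09 and lysozyme, Lyz2, at 1.46, while the Fc receptor gene Fcgr1 and the lipopolysaccharide co-receptor gene Cd14 stood at 1.79 and 1.85. The inflammatory polarisation list had a median of 0.51 (percentile 99.98), with ratios of 1.72 for Il1b and 1.98 for the prostaglandin synthase gene Ptgs2 and no measured member past 2-fold. Nos2, a member below the CPM minimum, had a ratio of 2.28 (1.65 to 3.18) from 52 UMIs in Blank and 155 in Col_nHA.

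Members of the alternative macrophage polarisation list went in opposite directions, and its median of -0.19 lay within the range of random lists (percentile 3.48). It lay below that range as a mean of per-spot CPM, at -0.47, and with no CPM minimum, at -0.26, but had the opposite sign without the spots rich in other tissues, at 0.04, and at 50 CPM, at 0.02. Its median was 0.57 (percentile 99.75) in region 6 and -1.42 (percentile 0) in region 9, the 2 regions compared further on, so no direction is drawn for it. Arg1, which encodes arginase 1, was 8.10 (7.40 to 8.88) times as abundant in Col_nHA, and the chitinase-like gene Chil3 3.65 (3.27 to 4.08) times. Among regions described further on, Arg1 in Col_nHA stood at 325 CPM in region 16, led by Krt6b. It stood at 160 CPM in region 10 and 88.9 CPM in region 12. The macrophage and monocyte list took 0.452%, 1.70% and 0.613% of the UMIs of these 3 regions. The Arg1 ratio can therefore not be read as a macrophage state alone. Retnla, Clec10a and the haemoglobin scavenger receptor gene Cd163 had ratios of 0.262, 0.291 and 0.415. The lysosome and phagocytosis list had a median of 0.46 (percentile 99.98), with the cysteine cathepsin genes Ctss at 2.57 and Ctsl at 2.495. The chemokine list had a median of 0.54 (percentile 100), with 4 of 16 members at least 2-fold higher. They were Cxcl5 at 3.12 (2.87 to 3.38), Ppbp at 2.76, Ccl2 at 2.68 (2.52 to 2.85) and Ccl3 at 2.08, whereas Ccl8 stood at 0.758. The interferon response list had a median of 0.31 (percentile 99.9), with Isg15 at 2.02 and Ifi27l2a at 1.01.

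The osteoclast and macrophage fusion list had a median log2 ratio of 1.22 (percentile 100), and 7 of its 10 measured members were at least 2-fold higher in Col_nHA. Acp5, which encodes tartrate-resistant acid phosphatase, stood at 890 CPM in Col_nHA and 386 CPM in Blank, a ratio of 2.31 (2.26 to 2.35). The ratio was 3.04 (2.86 to 3.23) for the proton pump subunit gene Atp6v0d2, 2.87 (2.42 to 3.42) for Oscar, 2.36 for the fusion gene Dcstamp and 1.45 (1.43 to 1.47) for cathepsin K, Ctsk. Mmp9, a gelatinase gene of osteoclasts and neutrophils, was 2.60 (2.53 to 2.66) times as abundant. The matrix degradation list, which shares Mmp9 and Ctsk with it, had a median of 0.68 (percentile 100), with Timp1 at 2.20 and Mmp2 at 0.734. The osteoclast differentiation factor Tnfsf11, also known as RANKL, had a ratio of 2.55 (2.12 to 3.07) from 510 UMIs in Col_nHA and 153 in Blank, and the ratio of Osm was 2.86. Both belong to the list of osteogenic and immune signals, whose median was 0.24 (percentile 99.8), and in the same list Igf1 stood at 0.619. With a minimum of 50 CPM the median of that list changed sign, to -0.04.

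The osteoblast and osteocyte list had a median log2 ratio of -0.07 (percentile 16.2), with 2 of 11 measured members at least 2-fold lower and none at least 2-fold higher. It lay below the range of random lists under 3 other settings, at -0.30 with a minimum of 50 CPM (percentile 0.55), at -0.30 with no CPM minimum (percentile 0.88) and at -0.16 without the spots rich in other tissues or choroid plexus genes (percentile 1.41). With no minimum 5 members were at least 2-fold lower, among them the osteocyte genes Phex, Sost and Mepe at 0.369, 0.372 and 0.471, each from fewer than 100 UMIs per section. The 2 measured members past 2-fold were the osteocalcin genes Bglap and Bglap2, at ratios of 0.404 (0.394 to 0.414) and 0.429 (0.414 to 0.446). These genes are neighbours with similar sequences, and how reads shared between them were assigned was not examined. Ibsp, which encodes bone sialoprotein, was 1.97 (1.88 to 2.06) times as abundant in Col_nHA, Alpl and Sp7 stood at 0.988 and 1.04, and Col1a1, the most abundant member, at 0.670. The skeletal progenitor and periosteum list lay lower in Col_nHA with a median of -0.45 (percentile 0.050), with Twist1 at 0.592 and Postn at 0.709. The fibroblast list lay lower as well, at -0.43 (percentile 0.020), with Dpt at 0.272 and Pi16 at 0.318. The myofibroblast and matrix assembly list at 0.01 (percentile 18.9), the pericyte and smooth muscle list at 0.08 (percentile 69.5) and the cartilage list at -0.60 (percentile 2.58) lay within the range of random lists, but the cartilage list lay below it without the spots rich in other tissues or choroid plexus genes, at -0.63 (percentile 1.62).

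The endothelial list was higher in Col_nHA, with a median log2 ratio of 0.30 (percentile 99.9), although none of its 12 members differed by 2-fold, and the ratios of the receptor genes Kdr and Flt1 were 1.68 and 1.54. Between spots of region 9 the endothelial list was lower in Col_nHA, at -0.27 (percentile 1.11), and in region 6 it lay within the random range at 0.18 (percentile 87.6). The lymphatic list was lower, at -1.23 (percentile 0.050), with 4 of 6 measured members at least 2-fold lower. Without the spots rich in other tissues its median was -0.53, with 1 of 5 members at least 2-fold lower. Cell cycle genes had a median of 0.88 (percentile 100), with all 12 members above 1 and ratios from 1.44 for Pcna to 2.14 for Tpx2. Hypoxia and glycolysis genes had a median of 0.79 (percentile 100), with Slc2a1 at 2.35 and Aldoa at 1.93. Skeletal muscle genes, which glycolytic fibres express, were higher in the same section. Without the spots rich in other tissues the median of the hypoxia and glycolysis list was 0.56, and the log2 ratio of Aldoa was 0.38. Immediate early and stress genes lay within the random range at -0.09 (percentile 12.3).

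Among other blood and immune lists, that of mast cells and basophils was lower in Col_nHA with a median log2 ratio of -2.84 (percentile 0), and the 4 of 6 measured members at least 2-fold lower were mast cell genes. The mast cell protease gene Mcpt4 stood at 55.1 CPM in Blank and 3.83 CPM in Col_nHA, and the chymase gene Cma1 at 42.1 and 5.67 CPM. The receptor gene Kit had a ratio of 0.938, and the basophil protease gene Mcpt8, below the CPM minimum, one of 5.24 (3.34 to 8.61) from 22 UMIs in Blank and 151 in Col_nHA. Erythroid genes were lower at -1.25 (percentile 0.030), with the globin gene Hba-a2 at 0.337. B and plasma cell genes were lower at -0.84 (percentile 0.57) over 4 measured members, with Ighm at 0.529, but with no CPM minimum the list lay within the random range at -0.53 (percentile 8.52). The dendritic cell list at -0.29 (percentile 4.56) and the T and NK cell list at -0.41 (percentile 10.7) lay within the random range, and single members of them differed, with Cd209a at 0.212 and Il7r at 3.53. The dendritic cell list lay below that range with no CPM minimum, at -0.67 (percentile 0.62), and as a mean of per-spot CPM, at -0.44 (percentile 2.14), and stood at -0.04 without the spots rich in other tissues. Without the spots rich in other tissues the median of the T and NK cell list was 0.47 (percentile 97.6), the opposite sign. The neutrophil list had a median of -0.39 (percentile 1.07), but its members were split, since S100a8 stood at 1.70 and Mmp9 at 2.60 while Wfdc21, a gene also known from epithelia, stood at 0.139. Of the S100a8 UMIs in Col_nHA, 37.9% lay in region 16, led by Krt6b and described further on. S100a8 can therefore not be read as a neutrophil transcript alone. Without the spots rich in other tissues the median of the neutrophil list was 0.03, so no direction is drawn for that list. List members named above that fall outside the naming rule, such as Itgax, Chil3, Cd163, Dcstamp, Osm and Ibsp, were chosen after their values were seen. In all, 23 of 32 lists stood apart from random lists, 12 higher and 11 lower.

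**Figure D1:**
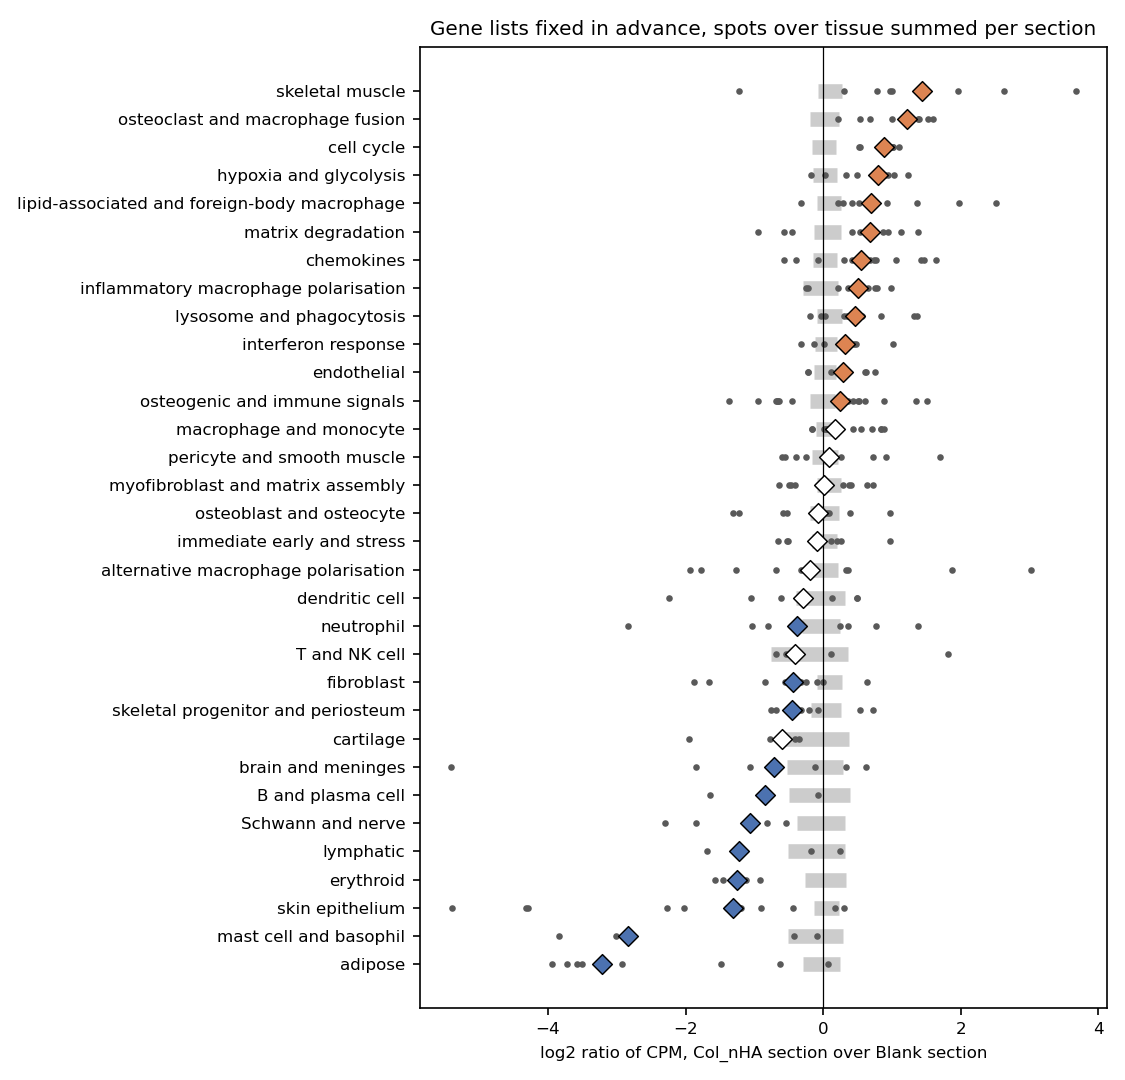
Median log2 ratio of CPM, Col_nHA over Blank, for each gene list (diamonds, orange above and blue below the central 95% of random lists, white within it), with the members as grey points and the central 95% of random-list medians as grey bars. The osteoclast and macrophage fusion list lies at 1.22 and the osteoblast and osteocyte list at -0.07.

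Transcripts of other tissues differed strongly between the sections. Of the 12 genes with the highest ratios among those with at least 50 CPM, 3 were keratin genes of wounded or stressed epidermis, Krt6b at 56.8 (47.1 to 69.0), Krt6a at 10.1 (9.53 to 10.8) and Krt16 at 5.55 (5.21 to 5.92). The cysteine protease inhibitor genes Stfa1, Stfa3 and BC100530 had ratios of 10.5, 6.46 and 5.25. The fast muscle genes Myh4, Mybpc2 and Pvalb stood at 12.8 (12.3 to 13.3), 6.24 and 6.17. Arg1, Spp1 and Gpnmb made up the rest of the 12. The skeletal muscle list had a median log2 ratio of 1.43 (percentile 100), with 8 of 12 members at least 2-fold higher, but Myh2, a myosin gene of other fast fibres, stood at 0.430, and Mybph, a muscle gene outside the list, was 13.1-fold lower. The skin epithelium list was lower in Col_nHA, at -1.30 (percentile 0), with 8 of 12 members at least 2-fold lower. Krt10 and Lor, genes of the keratinised layers, were 19.6-fold (18.3 to 21.1) and 19.97-fold (18.3 to 21.8) lower, and Krt15 was 42.3-fold (36.1 to 49.9) lower, whereas the basal keratin gene Krt14 stood at 1.13 (1.11 to 1.16).

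The 12 genes with the lowest ratios included genes of skin, fat, mast cells and choroid plexus, the tissue that makes cerebrospinal fluid. Ttr, which encodes transthyretin, had 332389 UMIs in Blank spots, 10825 CPM, and 26 UMIs in Col_nHA spots, 0.647 CPM. Enpp2 and Kl were 53.0-fold (49.3 to 57.0) and 234-fold (123 to 513) lower in Col_nHA. Krt77 had 8288 UMIs in Blank and 2 in Col_nHA, and Defb8 and Far2 were 96.3-fold and 13.4-fold lower. The adipose list had a median log2 ratio of -3.22 (percentile 0), with the adipsin gene Cfd 13.2-fold (12.2 to 14.2) lower. The Schwann and nerve list stood at -1.06 (percentile 0.020), and the brain and meninges list at -0.72 (percentile 0.88) with Ptgds at 1.53 and Mbp at 0.479. With a total that leaves out mitochondrial, ribosomal and haemoglobin genes, the brain and meninges list lay within the random range at -0.41 (percentile 5.67). By UMI share, 21.4% of Blank spots and 13.5% of Col_nHA spots held over 2% of their UMIs in the brain, muscle, skin, fat and nerve lists.

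**Figure D2:**
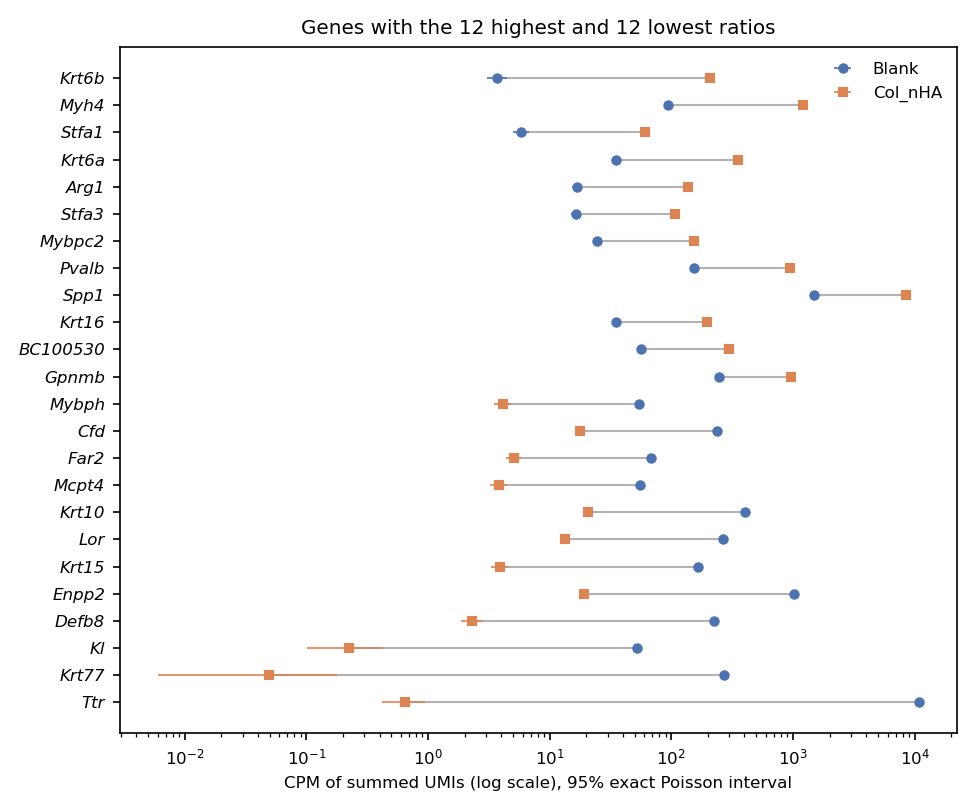
CPM of summed UMIs on a log axis for the genes with the 12 highest and 12 lowest ratios, Blank as circles and Col_nHA as squares, with exact 95% Poisson intervals that cover counting error only. Spp1 has the highest CPM of the upper 12 genes in both sections, and Ttr stands at 10825 CPM in Blank and 0.647 CPM in Col_nHA.

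By position in mouse assembly GRCm38.p6, the assembly behind mm10, Spp1 (ENSMUSG00000029304) is a protein-coding gene on chromosome 5 from 104435111 to 104441053. Gpnmb (ENSMUSG00000029816) lies on chromosome 6 from 49036518 to 49058182, Acp5 (ENSMUSG00000001348) on chromosome 9 from 22126727 to 22135746, and Arg1 (ENSMUSG00000019987) on chromosome 10 from 24915207 to 24927470. Bglap and Bglap2 lie beside each other on chromosome 3, from 88383495 to 88384466 and from 88377736 to 88378701.

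The share of spots with a UMI was compared after every spot was thinned to 2000 UMIs. Spp1 was found in 68.3% (66.3 to 70.2) of Blank spots and 93.6% (92.6 to 94.5) of Col_nHA spots, against 93.7% and 99.8% without thinning. Acp5 was found in 33.8% (31.8 to 35.8) and 50.9% (48.9 to 52.9), against 73.9% and 89.5% without thinning. Mcpt4 was found in 11.1% (9.85 to 12.5) and 1.09% (0.721 to 1.59), against 25.1% and 3.89% without thinning. Barcodes below the tissue threshold, thinned to 500 UMIs, held Spp1 in 45.9% of Blank and 90.8% of Col_nHA barcodes, more than the 33.9% and 77.3% of tissue spots at that depth, so an Spp1 UMI in a spot cannot be read as expression in that spot. The same limit holds for Acp5, found in 16.9% and 24.5% of these barcodes against 13.5% and 22.8% of tissue spots. It also holds for Mcpt4 in Col_nHA, at 0.514% against 0.364%. Bglap was found in 27.5% and 17.0% of these barcodes against 11.7% and 7.37% of tissue spots, so the limit holds for it too.

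The next comparison asked which spot profiles each section held and whether the differences were also seen between spots of like profile. Clustering both sections together gave 17 regions, and only 2 of them held at least 50 spots of each section. Region 6, led by Ptgdr, Shisa3, Col6a5, Cldn11 and Penk, held 9.74% (8.54 to 11.04) of Blank spots and 13.8% (12.5 to 15.3) of Col_nHA spots. Region 9, led by the bone-forming genes Bglap, Bglap2, Ifitm5 and Ibsp, held 5.38% (4.48 to 6.39) and 3.89% (3.16 to 4.72). Each of the other regions was held mostly by 1 section, so region and section are not separable there. In Blank these were led by Tnmd and Sfrp2 (region 1, 25.9% of Blank spots), Cfd and Cyp2e1 (region 2, 16.8%), Tnnc1, Myh8 and Myh3 (region 7, 12.3%), Defb8 (region 3, 9.16%), Lor (region 4, 8.58%), C3 (region 5, 6.63%) and Ttr (region 8, 2.89%). In Col_nHA they were led by Cnn1, Acp5 and Mmp9 (region 12, 17.0% of Col_nHA spots), Npy, Spp1 and Mmp12 (region 10, 12.7%), Saa3, Cxcl5 and Arg1 (region 13, 12.3%), Myh4 (region 11, 10.4%), Dlk1 (region 14, 9.11%), Krt6b (region 16, 7.85%), Tmem178, Ly6c2 and Cxcl10 (region 15, 6.35%) and Il1rl1 and Hmox1 (region 17, 4.86%).

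**Figure D3:**
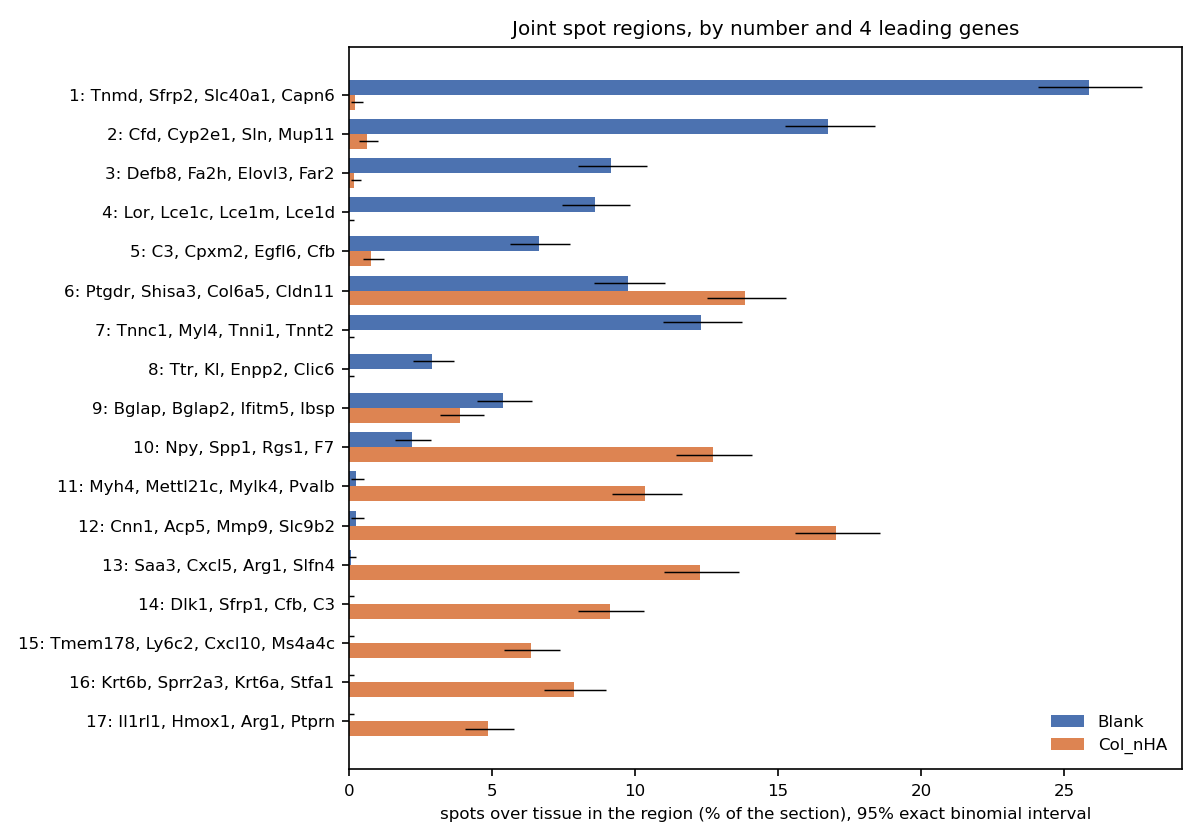
Share of the spots over tissue of each section (%) in each joint region, with exact 95% binomial intervals that cover counting error only, and 4 leading genes per region. Only regions 6 and 9 hold at least 50 spots of each section, and regions 4, 7 and 8 hold no Col_nHA spot.

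Shares of a gene in a region that it leads are not given, because the clustering used the same genes. Region 10, which Spp1 and Gpnmb help to lead, held 49 Blank spots. The levels of Spp1 and Gpnmb there are not compared between the sections, because these genes help to define the region. Its Blank spots also fell short of the minimum number set for ratios within a region.

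Between spots of region 9 the osteoclast list had a median log2 ratio of 0.15 (percentile 65.2), and Acp5 stood at 1691 CPM in Blank and 1716 CPM in Col_nHA, a ratio of 1.01 (0.960 to 1.07). The lipid-associated macrophage list also lay within the random range there, at 0.25 (percentile 82.1), with 3 members at least 2-fold higher and 2 at least 2-fold lower. The Spp1 ratio there was 1.96 (1.87 to 2.05) and the ratio of Gpnmb 2.35 (1.96 to 2.83). In Col_nHA these genes stood there at 3754 and 264 CPM, below their 8434 and 755 CPM in barcodes under the tissue threshold. Free RNA from other spots can therefore not be told apart from expression in the spots of region 9. Alpl, the alkaline phosphatase gene, stood at 1.51 (1.36 to 1.66), and Col1a1 at 0.779. Cell cycle genes kept a median above 0, at 1.13, and interferon response genes one of 0.93. Between spots of region 6 the osteoclast list had a median of 0.64 (percentile 99.95) and the lipid-associated macrophage list one of 1.03 (percentile 100). The osteoblast and osteocyte list was lower there, at -1.06 (percentile 0), and its median in region 9 is not read because several of its members lead that region. In region 6 the ratio of Spp1 was 6.63 (6.44 to 6.82) and that of Gpnmb 5.93 (5.53 to 6.36). Spp1 stood there at 1483 CPM in Blank and 9835 CPM in Col_nHA. In barcodes under the tissue threshold it stood at 1381 and 8434 CPM. Gpnmb stood at 253 and 1499 CPM in region 6, against 220 and 755 CPM in those barcodes. The Spp1 ratio in region 6 can therefore not be told apart from that of free RNA, and the Gpnmb ratio may share that limit. In region 6 the ratio of Ctss was 3.10 (2.95 to 3.26) and that of Bglap 0.171 (0.152 to 0.193). Bglap stood in region 6 at 340 CPM in Blank and 58.3 CPM in Col_nHA. Both values lie below its 870 and 464 CPM in barcodes under the tissue threshold. Its ratio there cannot be read as expression in these spots, and the osteoblast list median there may share that limit. Krt6b, an epidermal gene, was also higher in Col_nHA within region 6, with 60 UMIs against 2, and within region 9, with 66 UMIs against 0. Over both regions, 36 of 41 medians of the lists that stood apart in the whole sections had the same sign as there. Free RNA spread through a section could give the same sign in both regions, so the count cannot tell it from expression. The muscle gene Myh4, for example, stood in Col_nHA at 36.0 CPM in region 6 and 44.8 CPM in region 9. In Col_nHA barcodes under the tissue threshold it stood at 1061 CPM. The count is also of signs alone, and some of the medians with the same sign lay within the random range. In region 9 these were, by percentile, lipid-associated 82.1, osteoclast 65.2, osteogenic signals 63.7, chemokines 46.3, skeletal progenitor 17.25 and brain 6.26. In region 6 they were inflammatory polarisation 88.4, endothelial 87.6, matrix degradation 85.9 and osteogenic signals 78.35. The 5 with the opposite sign were all in region 9: neutrophil at 0.47, inflammatory polarisation at -0.04, endothelial at -0.27, lysosome and phagocytosis at -0.02 and skin epithelium at 0.10.

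**Figure D4:**
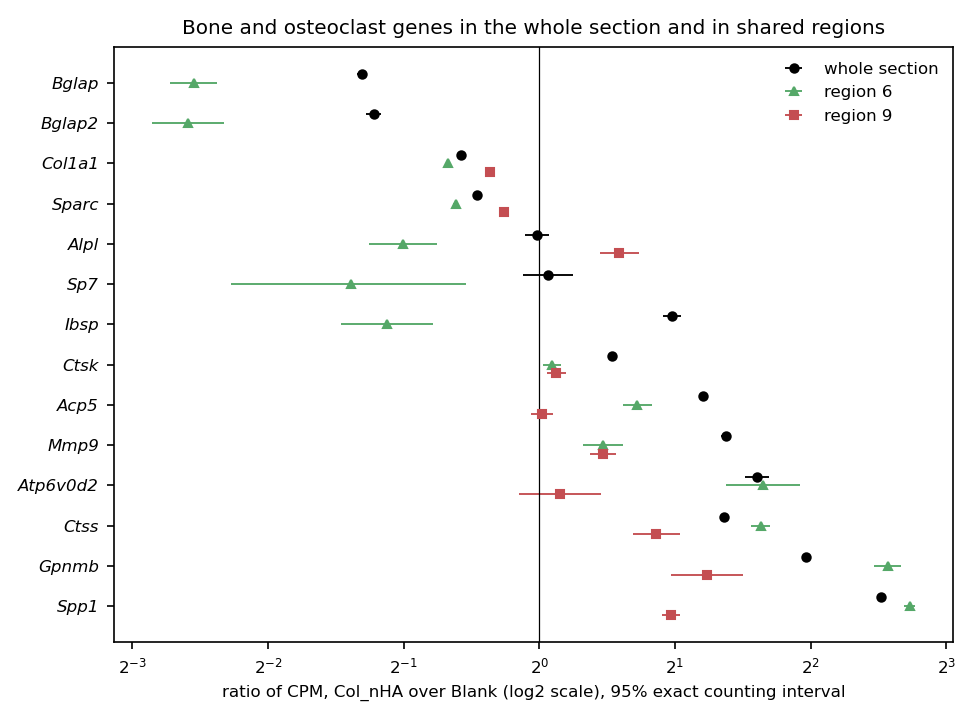
Ratio of CPM, Col_nHA over Blank, on a log2 axis for bone, osteoclast and macrophage genes of the fixed lists, picked for display after their values were seen, in the whole sections (circles), region 6 (triangles) and region 9 (squares), with exact 95% counting intervals. Genes that lead region 9 are not shown for it; Acp5 stands at 2.31 in the whole sections and 1.01 in region 9, and Spp1 at 5.74 and 1.96.

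The last comparison asked which lists varied together across the spots of a section, over 61 pairs of lists per section at 2000 UMIs per spot. Spots are not replicates and no p is given. The lipid-associated and macrophage lists had a Spearman rho of 0.51 in Blank and 0.81 in Col_nHA, and the lysosome and macrophage lists 0.57 and 0.82. The osteoclast list varied with the osteoblast list to a like degree in both sections, with a rho of 0.25 in Blank and 0.24 in Col_nHA. Its rho with the macrophage list was 0.08 and 0.21. By UMIs the osteoblast list was mostly Col1a1, at 31502.5 CPM in Blank and 21095.8 CPM in Col_nHA, against 578 and 233 CPM for Bglap. The osteoblast list varied most with the fibroblast list, at 0.75 and 0.83, and the myofibroblast list, at 0.70 and 0.76. Its rho values therefore cannot be read as relations to osteoblasts alone. The hypoxia and glycolysis list ran against the osteoblast list, at -0.28 and -0.32, and so did the skeletal muscle list, at -0.28 and -0.22.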

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

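Tests chosen only after the result was seen were those of depth, whose bounds were set before it was run, of other tissues in the sections, of amounts of tissue within regions, of the keratin genes and of choroid plexus tissue under spots.

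The barcodes below the tissue threshold are outside the comparisons and still held signal. They carried 11.9% of all UMIs in Blank and 10.9% in Col_nHA. Gm42418, a transcript with ribosomal RNA sequence, took 7.53% of their UMIs in Blank and 4.69% in Col_nHA, against 1.26% and 0.629% over tissue. The Spp1 log2 ratio among them was 2.61, against 2.52 over tissue. Ttr took 0.434% of their UMIs in Blank.

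Spp1, Gpnmb and the osteoclast and macrophage fusion list were higher in the Col_nHA section. Between spots of like total UMIs, in 4 bins, the lowest ratios were 5.29 (5.22 to 5.36) for Spp1 and 3.09 (2.93 to 3.25) for Gpnmb. The lowest osteoclast list median was 0.85, so the differences were seen at each depth. These values met the bounds set against greater depth per spot as the cause. CPM already divides by depth, however, so the test could hardly have failed and draws no conclusion. Without the spots rich in other tissues or choroid plexus genes, the Spp1 ratio was 5.26 (5.21 to 5.31) and the osteoclast list median 1.13. The differences were thus also seen without those spots. Of 2249 Blank spots 1582 were kept, however, so the Spp1 ratio could hardly have fallen to the bound set. No further conclusion on other tissues taking up Blank counts is drawn. Different amounts of the same kinds of tissue cannot be told apart from the treatment. The Spp1 ratio was 1.96 (1.87 to 2.05) in region 9 and 6.63 (6.44 to 6.82) in region 6. However, spots hold several cells, the macrophage list was itself higher in region 6 (median 0.75), and the osteoclast list lay at 0.15 in region 9. Free RNA cannot be told apart in region 6 or region 9 either. In region 6 the Spp1 log2 ratio was 2.73, against 2.61 in barcodes under the tissue threshold. Col_nHA Spp1 stood in region 9 at 3754 CPM, below its 8434 CPM in those barcodes. Across Col_nHA spots the rho of Spp1 was 0.63 with the other lipid-associated macrophage genes and -0.11 with the osteoblast list, a difference of 0.74. This goes with Spp1 UMIs lying where macrophage genes are abundant in that section. In Blank the difference was 0.13 (0.22 against 0.09), below the bound of 0.2 set for Col_nHA. With Bglap, Bglap2, Ibsp and Ifitm5 alone, the rho of Spp1 was 0.19 in Blank and -0.07 in Col_nHA. A response to the material stays open and untested.

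Keratinocyte genes moved apart between the sections. More skin in the Blank section would give these genes a like ratio, but the section ratio of Krt14 was 22.2 (20.3 to 24.4) times that of Krt10, which argues against it as the whole account. Skin of another state or layer in each section may remain, and wounding, the plane of the section and the material were not tested.

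Ttr and other choroid plexus genes were abundant in the Blank section alone, where 133 spots held over 2% of their UMIs in Ttr. Of 6566 UMIs of 9 other choroid plexus genes, 84.7% (83.8 to 85.6) lay in these spots, chosen by Ttr alone after a test by region had been seen, against 5.56% of all Blank UMIs, which is consistent with choroid plexus tissue under them. Ttr was found in 99.2% of Blank spots. Its UMIs per UMI of those genes outside region 8, which such genes lead, were 0.583 (0.550 to 0.618) of those inside. This lay within the 2-fold set beforehand for free RNA from that tissue. Region 8 held 65 spots, however, so some of the 133 spots rich in Ttr were counted as outside it. A like value would also come from choroid plexus tissue under them, so the test cannot tell free RNA from tissue. No biological explanation was tested.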

How the results depend on the processing

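No paired analysis was possible because each group has 1 section, and no library could be left out. Of 23 lists that stood apart, 18 did so in the same direction under every setting run on lists that gave a value; the Gaussian mixture was compared on numbers of spots alone, and 12 lists had too few members at 50 CPM. Leaving out choroid plexus spots was chosen after seeing the data. Where nothing is said, the cause was not tested. At 500 UMIs each section kept 4806 barcodes. Genes 2-fold higher and lower numbered 1558 and 2972 with no CPM minimum and 72 and 96 at 50 CPM, where more or fewer genes were counted; 211 were lower without other tissues or choroid plexus. Without spots rich in other tissues the medians were 0.028 for neutrophils (no longer apart), 0.29 for macrophages and 0.47 for T and NK cells (both now apart). For skeletal muscle, a list that the filter itself uses, the median had the opposite sign, at -1.02, with Ckm at -0.35. With choroid plexus spots left out too the medians were -0.064 for neutrophils (no longer apart), -0.16 for osteoblasts and -0.63 for cartilage (both now apart) and -0.997 for muscle, with Ckm at -0.27. With no CPM minimum they were -0.069 for neutrophils and -0.53 for B cells (both no longer apart), -0.26 for alternative macrophages, -0.67 for dendritic cells and -0.30 for osteoblasts (all now apart). At 50 CPM they were -0.30 for osteoblasts (now apart) and -0.039 for osteogenic signals (no longer apart). As a mean per spot they were -0.47 for alternative macrophages and -0.44 for dendritic cells (both now apart). With the reduced total, brain stood at -0.41 (no longer apart), as the members past the CPM minimum changed. A resolution of 0.3 gave 11 regions, with 29 of 39 medians in the same direction. Of the log2 ratios of named genes over all settings, 674 stayed within the counting interval, 395 moved outside it and 2 reversed. Depth moved 233 shares of spots outside their counting intervals and 40 rho values by at least 0.1. The lipid-associated and macrophage lists had a rho of 0.62 in Blank and 0.88 in Col_nHA without thinning and 0.30 and 0.64 at 500 UMIs; the osteoclast and osteoblast lists 0.38 and 0.31, and 0.13 and 0.15.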

Other observations

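In Blank, region 2, which Myh2 helps to lead, held 79.5% of the Myh4 UMIs, at 493 CPM of Myh4. Region 7, held by Blank spots alone, was led by Tnnc1, Myl4, Myh8 and Myh3, genes of slow, embryonic and newborn fibres, with Mymk and Myog, which act in fusing and differentiating muscle cells. Region 11, which held 10.4% of Col_nHA spots and 0.222% of Blank spots, was led by Myh4 and Pvalb, genes of the fastest fibres. Mitochondrial transcripts took 3.67% of the UMIs over tissue in Blank and 4.60% in Col_nHA.

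Within region 9, the haemoglobin gene Hbb-bs had a ratio of 0.232 and Apoe a ratio of 0.418. Within region 6, Lyz2 had a ratio of 2.17 (2.13 to 2.22), and the macrophage and monocyte list had a median log2 ratio of 0.75, while it was -0.16 in region 9. These were picked after their values were seen.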
